A study of Homo sapiens with 16 samples.

How the data were processed

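RNA of SKOV3 cells was collected after 24 h with DMSO or 10 ng/ml IFN-γ, and libraries were made from poly(A)-selected RNA with a kit that keeps strand, per the labels' protocols. The 16 libraries form 4 groups of 4, wild-type or labelled IDO1 knock-down under each treatment, and each was placed by its own labels. The knock-down method and the number of knock-down lines are not given in the sources used here.

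The authors deposited a single table of normalized gene counts for all libraries, treated here as a signal in the units of normalized reads per gene. Per the submitters' processing notes the tools were STAR 2.7.10b, HTSeq, DESeq2, DESeq 1.42.0 and R 4.3.3 with the build GRCh38. Their roles, the strand setting of the counting, the annotation release and any filter on genes are not given in the sources used here. Without a stated strand setting, a gene and an overlapping or antisense gene may share counts. The table has 19671 Ensembl gene identifiers, of which 19594 were named from a table of gene names and 19382 were found in GENCODE release 29, the source of the positions and types given here. No identifier has only zeros, and 7 were in neither source.

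In each library the deposited values are whole multiples of a single step, the worth of 1 read. Dividing by that step gave whole reads within a tolerance of 0.1 for 100% of the values. The steps correspond to size factors of 0.606 to 1.85, a 3.06-fold range, and differ by at most 0.474% from median-of-ratios factors computed on the recovered reads. The recovered totals ran from 11501954 to 33349098 reads per library, and 5 libraries had under 13000000. For a gene without a read in a group, the level of 3 reads over the group was used as a floor, which is 0.645 normalized reads in wild-type DMSO, 0.659 in wild-type IFN-γ, 0.806 in labelled knock-down DMSO and 0.549 in labelled knock-down IFN-γ libraries. Pairs of replicates within each group were compared by a chi-square test of their counts over genes, and all 24 pairs differed by more than sampling noise, with 3.31 to 9.32 per degree of freedom.

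Values were tested as log2(value + 1) without further scaling, over the 17246 genes with a value of at least 10 in at least 4 libraries. All 16 libraries entered a single limma model (limma 3.58.1, R 4.3.3, eBayes with trend and robust) with a mean per group. The 5 contrasts were IFN-γ against DMSO in wild-type cells, the same in the cells labelled knock-down, labelled knock-down against wild-type under IFN-γ, the same under DMSO, and the difference of the IFN-γ responses. Two-sided p-values were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. IDO1 was also tested by an exact two-sided permutation test over the 70 arrangements of 4 against 4 libraries. Python 3.11.15 was used to read the table.

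Gene lists of pathways, of cell type markers and of signs of RNA quality were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes, except where the text says otherwise. Of 29 lists, the 28 with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. The named genes are IDO1, for each contrast the 10 genes with the highest and the 10 with the lowest log2 difference, and members of the lists. The first kind had to pass the threshold, reach a mean of 50 in a group and, except for the difference of responses, show no overlap between the groups compared. From each list up to 4 passing members with the largest change and up to 2 others with the highest mean could be named, all tested tryptophan and kynurenine enzymes, and fixed genes, among them IRF1, CXCL10, CD274, HLA-DRA, CIITA, AHR, CYP1B1, ATF4 and WARS1. CYP1A1, also fixed, did not pass the filter on low values. Some genes that this rule allows are not reported here.

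HSPA1A and HSPA1B, the HLA genes, the guanylate-binding proteins, the CGB genes, the AKR1C genes and UGT1A6 share sequence with close relatives, so their separate counts are uncertain.

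The alternatives tried were pseudocounts of 0.5 and 5, no filter on low values or a mean of at least 50, TMM and quantile scaling, the replicate number as a block, the 8 libraries of a comparison alone, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, eBayes without trend and robust, stricter thresholds, and leaving out each library in turn. Chosen after seeing the data were the fits without the 5 shallowest libraries, on reads thinned to the lowest library total, and with a loess trend (span 0.5) of GC content and transcript length removed, which was possible for 17062 of the 17246 genes (98.9%).

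The test was run on simulated counts for the contrast of wild-type cells, with 200 genes changed. Counts were drawn for each gene independently, from the wild-type DMSO means, the real size factors and a single dispersion. Of 16857 genes tested, 57 of 67 changed 1.5-fold were called (85.1%), 66 of 67 changed 2-fold (98.5%) and 66 of 66 changed 4-fold, with 4 false calls. With limma, 0 genes were called in each of the unchanged comparisons simulated beside it, IFN-γ in the cells labelled knock-down and labelled knock-down against wild-type under DMSO. Camera called the 1 list changed 1.5-fold and 0 of the 27 others. Since the simulated genes were independent, this does not show how camera behaves on lists whose genes vary together.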

Results

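Poly(A)-selected RNA was sequenced from SKOV3 cells, an established human ovarian carcinoma line, either wild-type or labelled as an IDO1 knock-down, after 24 h with DMSO or with 10 ng/ml IFN-γ, the type II interferon. IDO1 encodes indoleamine 2,3-dioxygenase, which starts the breakdown of tryptophan to kynurenine. The 4 groups held 4 libraries each, and the whole reads recovered from the deposited values came to 11501954 to 33349098 per library. Adjusted p-values of single genes are limma's. Levels are normalized read counts, given as mean ± SD of the 4 libraries of a group unless said otherwise. Folds are ratios of group means, and log2 values are differences on the log2(value + 1) scale, which understates the change of low genes. Floors given here cover counting error only. No source used here says whether the 4 libraries of a group came from separate cultures. The p-values of single genes therefore measure the spread between these libraries, which may be technical. Those of camera compare the genes of a list with other genes at a preset correlation. They therefore rest mainly on the spread between genes, and very small ones are not a measure of replication.

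IDO1 (ENSG00000131203, GRCh38 chromosome 8, 39902275 to 39928444) was read in every library as a check on the labels. Under DMSO it stood at 321 ± 35.3 (SD, n = 4) in wild-type cells and at 31.9 ± 9.90 in the libraries labelled knock-down, a 10.1-fold lower level with no overlap between the groups. Under IFN-γ it stood at 23430.1 ± 873 in wild-type cells and at 26976 ± 425 in the libraries labelled knock-down, 1.15-fold higher, again with no overlap. IFN-γ thus raised the transcript 72.9-fold in wild-type cells and 846-fold in the cells labelled knock-down. In an exact two-sided permutation test of the log2 values p was 0.0286 under each treatment, the smallest value 4 against 4 libraries can give. In the limma model over all genes the difference was -3.34 (SE 0.17, adjusted p = 1.4e-08) on the log2 scale under DMSO and 0.20 (SE 0.17, adjusted p = 0.36) under IFN-γ, where a limma fit of only the 8 IFN-γ libraries gave an adjusted p of 7.2e-06, edgeR 1.7e-04 and DESeq2 2.1e-06. The transcript level under IFN-γ therefore goes against the label, and the affected libraries are called the libraries labelled knock-down here. Reads of a transcript carry no measure of the protein or its activity.

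**Figure D1:**
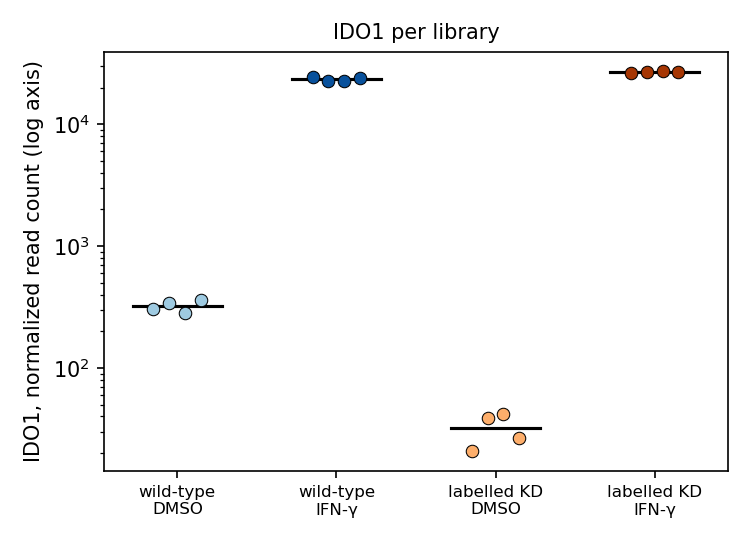
IDO1 per library as normalized read count on a log axis, with 4 libraries (points) and their mean (line) for each of the 4 groups. Under DMSO the libraries labelled knock-down lie between 20.6 and 41.5 against 282 to 361 in wild-type cells, and under IFN-γ between 26559 and 27565 against 22654 to 24439.8.

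The response of wild-type cells to the cytokine was read from the IFN-γ and DMSO libraries. Genes of MHC class II and the guanylate-binding proteins rose from low levels. CD74, the invariant chain that accompanies class II molecules, went from 6.02 ± 2.37 to 5235 ± 118 (SD, n = 4, 869-fold), and GBP1, an interferon-induced GTPase, from 88.7 ± 3.92 to 17025 ± 321 (192-fold). Alongside, genes of the amino-acid response rose, such as CHAC1, a glutathione-degrading enzyme (52.6 ± 17.97 to 1871 ± 126, 35.5-fold), and so did inflammatory cytokines such as IL6 (62.4 ± 19.6 to 1137 ± 54.5, 18.2-fold). The chaperone genes HSPA1A and HSPA2 fell to 871 ± 108 from 11238 ± 403 and to 80.6 ± 6.97 from 939.6 ± 32.9, and sterol genes such as INSIG1 fell to 647 ± 22.6 from 1876 ± 89.8. In total 9032 of the 17246 genes tested passed an adjusted p of 0.05, of which 4667 rose and 4365 fell. The share that rose, 51.7%, was 44.02% after quantile normalization and 47.2% after removal of a trend with GC content and length, an alternative chosen after seeing the data. At least 2-fold changes were found for 930 that rose and 808 that fell. On GRCh38, GBP1 (ENSG00000117228) lies on chromosome 1, 89052319 to 89065360, CD74 (ENSG00000019582) on chromosome 5, 150401637 to 150412929, CHAC1 (ENSG00000128965) on chromosome 15, 40952962 to 40956519 and IL6 (ENSG00000136244) on chromosome 7, 22725884 to 22732002. HSPA1A (ENSG00000204389) lies on chromosome 6, 31815464 to 31817946, beside its near-identical copy HSPA1B, and INSIG1 (ENSG00000186480) on chromosome 7, 155297776 to 155310235.

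The interferon genes moved together in wild-type cells. All 22 tested members of the list of IFN-γ effectors rose (22 adjusted over the list alone, camera adjusted p = 7.4e-30). GBP4 was counted with 2 reads over the 4 DMSO libraries and stood at 1149 ± 57.8 under IFN-γ, and GBP5 rose 95.1-fold and GBP2 44.03-fold. All 29 tested members of the list of type I interferon response genes rose (29 adjusted over the list alone, camera adjusted p = 2.1e-21). Among them IFI44L and RSAD2, an antiviral radical SAM enzyme, stood at 7.29 and 5.37 on the log2 scale. Of the MHC class II list 15 of 16 members rose (15 adjusted over the list alone, camera adjusted p = 2.2e-13). RFXAP, a subunit of the complex that binds class II promoters, did not pass (0.19, adjusted p = 0.40). HLA-DRA and HLA-DPA1 had no read in the 4 DMSO libraries and reached 231 ± 24.1 and 484 ± 45.5, at least 358-fold and 751-fold above the level that 3 reads over the group give. HLA-DRB1 went from 4 reads to 368 ± 35.2, and CIITA, the coactivator of class II transcription, rose 29.4-fold. Of the class I processing list 21 of 22 rose and 1 fell (21 rose adjusted over the list alone, camera adjusted p = 1.4e-26). The peptide transporter gene TAP1 rose 17.4-fold and the immunoproteasome subunit PSMB9 13.2-fold. The signalling list held 11 genes that rose and 3 that fell among 16 (11 rose adjusted over the list alone, camera adjusted p = 1.4e-04). The transcription factor IRF1 rose 19.4-fold, while the kinase JAK1 stood at -0.01. Of the checkpoint ligands 9 rose and 3 fell among 13 (9 rose adjusted over the list alone, camera adjusted p = 7.7e-04). CD274, the gene of PD-L1, rose 89.3-fold. Others among the 10 largest rises were APOL4 (8.27), BATF2 (7.86), the complement inhibitor SERPING1 (7.70) and SLC15A3 (7.60), an endolysosomal peptide transporter.

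Further groups rose in the same libraries. Of the amino-acid response list, targets of the transcription factor ATF4, 30 of 34 genes rose and 2 fell (30 rose adjusted over the list alone, camera adjusted p = 3.0e-22). STC2 rose 31.9-fold, ATF3 24.1-fold, the stress cytokine GDF15 12.7-fold and ATF4 itself 4.03-fold, from 3022 ± 65.7 to 12185 ± 349. Cytosolic tRNA synthetases followed with 15 of 19 genes up and 1 down (15 up adjusted over the list alone, camera adjusted p = 7.0e-10). CARS1 rose 4.28-fold and GARS1 2.98-fold. WARS1, the tryptophanyl-tRNA synthetase that IFN-γ is known to induce, rose 34.1-fold to 72084 ± 2129. All 17 tested NF-κB targets rose (17 adjusted over the list alone, camera adjusted p = 2.3e-14), such as the adhesion gene ICAM1 (49.1-fold), TNFAIP3 (14.6-fold) and CXCL8 (12.7-fold). Of the chemokines and cytokines 20 of 22 rose (22 adjusted over the list alone, camera adjusted p = 3.2e-12). IL1A rose 31.1-fold, and CXCL10 went from no read to 49.4 ± 17.9, at least 76.6-fold above the level of 3 reads. The list of apoptosis and pyroptosis genes was higher (15 rose and 1 fell of 23; 15 rose adjusted over the list alone, camera adjusted p = 1.8e-07). So was that of nucleic acid sensors (5 and 1 of 8; 5 rose adjusted over the list alone, camera adjusted p = 0.015), with AIM2 going from 2 reads over the 4 DMSO libraries to 51.8 ± 6.95 and TLR3 at 3.78 on the log2 scale. The p53 target list was called higher (9 rose and 4 fell of 14; 9 rose adjusted over the list alone, camera adjusted p = 0.044), but with adjusted p = 0.12 with an estimated correlation. AHR, the receptor that binds kynurenine, rose 2.38-fold, whereas CYP1B1, an enzyme gene under its control, fell by 0.58 on the log2 scale.

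Lower under IFN-γ in wild-type cells were genes of sterol synthesis, the cell cycle and the oxidative stress response. Of the cholesterol synthesis list 22 of 23 genes fell (22 adjusted over the list alone, camera adjusted p = 4.0e-16), including INSIG1 (-1.53), MVK (-1.29) and HSD17B7 (-1.27). S-phase genes fell in 19 of 24 cases and rose in 1 (20 fell adjusted over the list alone, camera adjusted p = 4.8e-07), such as CCNE2 (-0.96). Likewise 20 of 25 mitotic genes fell (20 adjusted over the list alone, camera adjusted p = 1.0e-06), such as KIF20A (-0.89). NRF2 targets fell in 16 of 20 cases and rose in 2 (17 fell adjusted over the list alone, camera adjusted p = 4.8e-08), with the aldo-keto reductases AKR1C3 and AKR1B10 at -2.45 and -2.36. In the same libraries 12 of 13 transcripts encoded in the mitochondrial genome, taken as a sign of RNA quality, fell (12 adjusted over the list alone, median -0.26, camera adjusted p = 1.4e-04, and adjusted p = 0.30 with an estimated correlation). So did 14 of 25 ribosomal protein genes (14 adjusted over the list alone, camera adjusted p = 0.0012, and adjusted p = 0.54 with an estimated correlation). Among the 10 largest falls of single genes were those of KLHL14 (-4.67), the transporter gene SLC47A2 (-3.99), WDR72 (-3.70), HSPA1A (-3.70), HSPA1B (-3.54), HSPA2 (-3.53) and the glucuronosyltransferase UGT1A6 (-3.15).

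Among the enzymes of tryptophan and kynurenine metabolism 4 of 10 rose and 1 fell in wild-type cells (4 rose adjusted over the list alone, camera adjusted p = 0.58). The 4 were IDO1, IDO2 (2.07), the amino-acid oxidase IL4I1 (1.49) and KYAT3 (0.53), and the 1 that fell was QPRT (-0.85), an enzyme of NAD synthesis. IDO2 was read at only 11.9 ± 4.73 under IFN-γ, and without wild-type DMSO replicate 2 its adjusted p was 0.053, with reads thinned to the lowest library total 0.29. Lists not called as a whole were those of NAD metabolism (5 rose, 3 fell of 12; 5 and 3 adjusted over the list alone) and AHR targets (5 and 4 of 10; 5 and 5 adjusted over the list alone). Nor were ferroptosis regulators (5 and 7 of 15; 5 and 7 adjusted over the list alone) and adhesion and mesenchymal genes (7 and 6 of 23; 7 and 6 adjusted over the list alone). The same held for hypoxia and glycolysis genes (7 and 4 of 20; 7 and 4 adjusted over the list alone) and ovarian epithelial markers (8 and 2 of 15; 8 and 2 adjusted over the list alone). It also held for fibroblast and endothelial markers (1 and 3 of 5; 1 and 3 adjusted over the list alone) and immediate early stress genes (4 and 5 of 12; 4 and 6 adjusted over the list alone). None of the 14 immune cell markers passed the filter on low values. Of 28 lists tested with camera, 13 were higher and 6 lower, and with an estimated correlation 12 and 4.

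The same comparison was made in the libraries labelled knock-down. The interferon genes rose there as well. CD74 went from 6.37 ± 2.87 to 7337 ± 117 (SD, n = 4, 1152-fold), GBP1 from 35.2 ± 15.7 to 18594 ± 895 (528-fold) and IRF1 from 322 ± 12.1 to 9898 ± 287 (30.7-fold). CHAC1 stood at 37.8 ± 5.42 without and 50.7 ± 8.83 with IFN-γ (log2 0.41, adjusted p = 0.079, or 0.039 without replicate 2 of that IFN-γ group and 0.041 without wild-type DMSO replicate 2) and ATF4 at 2399 ± 78.9 and 2501 ± 116 (log2 0.06, adjusted p = 0.33). In total 4875 of 17246 genes passed, 2597 higher and 2278 lower, with 689 and 176 of them changed at least 2-fold. The share of higher calls, 53.3%, was 38.6% after quantile normalization and 33.02% after removal of a trend with GC content and length, an alternative chosen after seeing the data.

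All 22 IFN-γ effectors rose in the cells labelled knock-down (22 adjusted over the list alone, camera adjusted p = 3.8e-62). All 29 type I interferon response genes (29 adjusted over the list alone, camera adjusted p = 1.7e-49) rose too. The same held for all 22 class I processing genes (22 adjusted over the list alone, camera adjusted p = 2.2e-61). So did 15 of 16 class II genes (15 adjusted over the list alone, camera adjusted p = 5.8e-26) and 9 of 13 checkpoint ligands (9 adjusted over the list alone, camera adjusted p = 3.3e-08), with CD274 up 62.7-fold. GBP4 and HLA-DPA1 had no read under DMSO there and reached 3236 ± 91.8 and 727 ± 11.3, at least 4013-fold and 902-fold above the level of 3 reads over the group. WARS1 rose 45.5-fold to 86897 ± 2178. Signalling components rose in 9 of 16 cases and fell in 1 (10 rose adjusted over the list alone, camera adjusted p = 8.0e-10). Of the amino-acid response genes 6 rose and 7 fell among 34 (6 and 7 adjusted over the list alone, camera adjusted p = 0.77). ATF3 was among those that rose, 4.49-fold, and SLC7A11, the cystine transporter, among those that fell (-1.59). Of the NF-κB targets 6 rose and 3 fell among 17 (7 and 3 adjusted over the list alone, camera adjusted p = 0.071), with ICAM1 up 42.8-fold and CXCL8 at 91.5 ± 16.4 under DMSO and 68.3 ± 11.3 under IFN-γ. Cholesterol synthesis genes rose in 6 and fell in 3 of 23 cases (7 and 3 adjusted over the list alone, camera adjusted p = 0.71), and INSIG1 rose by 0.41. Lower were 18 of 25 mitotic genes (18 adjusted over the list alone, camera adjusted p = 7.2e-10) and 14 of 20 NRF2 targets (14 adjusted over the list alone, camera adjusted p = 1.7e-12), such as PLK1 (-0.55) and AKR1C3 (-1.62). S-phase genes were called higher (10 rose and 1 fell of 24; 10 rose adjusted over the list alone, camera adjusted p = 0.014), with adjusted p = 0.17 with an estimated correlation. Among the 10 largest single falls were those of UGT1A6 (-4.14), RASSF9 (-2.41), the aggrecanase ADAMTS5 (-2.27), TNFRSF11B (-2.11), the gene of osteoprotegerin, and the near-identical chorionic gonadotropin genes CGB1, CGB2 and CGB7 (-1.87, -1.98 and -1.85). Among ribosomal protein genes 19 of 25 fell as well (21 adjusted over the list alone, camera adjusted p = 1.6e-08, and adjusted p = 0.23 with an estimated correlation). Of the 28 lists, 11 were higher and 4 lower, and 9 and 2 with an estimated correlation.

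Of the genes that rose in wild-type cells 1641 also rose in the cells labelled knock-down, against 703 for independent lists, and of those that fell 1366 also fell, against 577. The calls ran in opposite directions for 337 genes that rose and 247 that fell in wild-type cells. No library enters both comparisons.

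**Figure D2:**
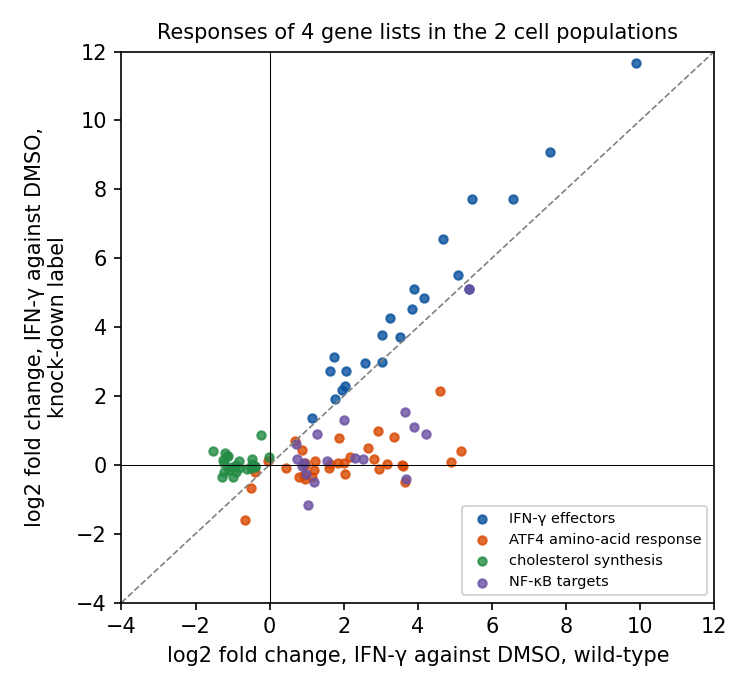
Log2 fold change under IFN-γ in wild-type cells (horizontal) and in the cells labelled knock-down (vertical) for the tested members of 4 lists, with the line of equal response dashed. GBP1 among the IFN-γ effectors lies at 7.57 and 9.10, CHAC1 among the amino-acid response genes at 5.18 and 0.41.

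The comparison the series title names, genes that depend on IDO1 under IFN-γ, sets the libraries labelled knock-down against wild-type under the cytokine. Most NF-κB targets and amino-acid response genes, and part of the chemokines and cytokines, were lower in the libraries labelled knock-down. CXCL8, a neutrophil chemokine, stood at 68.3 ± 11.3 against 3082 ± 226 (SD, n = 4, 45.1-fold lower), IL1A at 9.86 ± 6.83 against 937 ± 104 (95.04-fold lower) and CHAC1 at 50.7 ± 8.83 against 1871 ± 126 (36.9-fold lower). Sterol and S-phase genes were higher, such as INSIG1 (2699 ± 61.7 against 647 ± 22.6, 4.17-fold) and PCNA (5441 ± 70.3 against 2369 ± 53.2, 2.30-fold), and so were HSPA1A (7.14-fold) and HSPA2 (7.44-fold). In total 8433 of 17246 genes passed, 4289 higher and 4144 lower, with 726 and 542 of them at least 2-fold. The share of higher calls, 50.9%, was 52.7% after quantile normalization and 47.5% after removal of the trend with GC content and length. IDO1 itself was 1.15-fold higher, so the direction of these differences rests on the label and not on the level of the IDO1 transcript.

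Of the amino-acid response list 32 of 34 genes were lower in the libraries labelled knock-down and 0 higher (32 lower adjusted over the list alone, camera adjusted p = 1.3e-32, median -1.71). GDF15 was 40.3-fold lower, DDIT4, an inhibitor of mTORC1 signalling, 17.9-fold, PHGDH, the first enzyme of serine synthesis, 17.4-fold, and ATF4 4.87-fold (2501 ± 116 against 12185 ± 349). Cytosolic tRNA synthetases were lower in 16 of 19 cases and higher in 1 (16 lower adjusted over the list alone, camera adjusted p = 1.4e-11), with CARS1 at -2.04 and AARS1 at -1.71. WARS1 was 0.27 higher on the log2 scale (adjusted p = 1.6e-06), a difference that turned to -0.01 after quantile normalization. NF-κB targets were lower in 15 of 17 cases (15 adjusted over the list alone, camera adjusted p = 4.0e-15), including IL6 (15.3-fold) and CXCL2 (23.5-fold). Of the chemokines and cytokines 11 were lower and 8 higher among 22 (11 and 8 adjusted over the list alone, camera adjusted p = 0.029, and adjusted p = 0.17 with an estimated correlation). AHR targets were lower in 7 of 10 cases and higher in 2 (7 lower adjusted over the list alone, camera adjusted p = 0.0016), with the growth factor EREG 17.4-fold and AHR itself 2.37-fold lower, and CYP1B1 0.21 higher on the log2 scale.

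All 24 S-phase genes were higher in the libraries labelled knock-down (24 adjusted over the list alone, camera adjusted p = 4.3e-14), such as CCNE2 (1.29) and FEN1 (0.99). So were 20 of 23 cholesterol synthesis genes (20 adjusted over the list alone, camera adjusted p = 1.8e-18), such as HMGCS1 (1.57). Class I processing genes were higher in 18 of 22 cases (18 adjusted over the list alone, camera adjusted p = 5.4e-07), with the chaperone CALR at 0.70 and TAPBP, the gene of tapasin, at 0.47. Type I interferon response genes were called higher (12 of 29, and 12 adjusted over the list alone, camera adjusted p = 0.0068), among them IFIT1 (0.98). With an estimated correlation the camera adjusted p of that list was 0.37. The IFN-γ effectors were not called as a list (10 higher and 5 lower of 22; 10 and 5 adjusted over the list alone, camera adjusted p = 0.15), with GBP4 at 1.49, nor were the class II genes (4 and 1 of 16; 4 and 1 adjusted over the list alone, camera adjusted p = 0.18). All 13 mitochondrially encoded transcripts were higher beside the sterol and S-phase genes (13 adjusted over the list alone, median 0.52, camera adjusted p = 7.2e-09, and adjusted p = 0.20 with an estimated correlation). Among the 10 largest single rises were those of the cadherin CDH23 (40.1-fold, 322 ± 29.3 against 8.03 ± 2.83), WDR72 (13.4-fold), the matrix protein gene HMCN1 (3.71 on the log2 scale), NRN1 (11.9-fold) and IGFBP2 (8.98-fold). The largest falls besides those above included INHBE (136 ± 20.1 in wild-type cells, 5 reads in the 4 libraries labelled knock-down), BNC1 (50.6 ± 6.78 and 4 reads), KLHDC7B (47.4-fold) and IL1B (37.4-fold). Of the 28 lists, 5 were higher and 5 lower, and 3 and 4 with an estimated correlation.

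**Figure D3:**
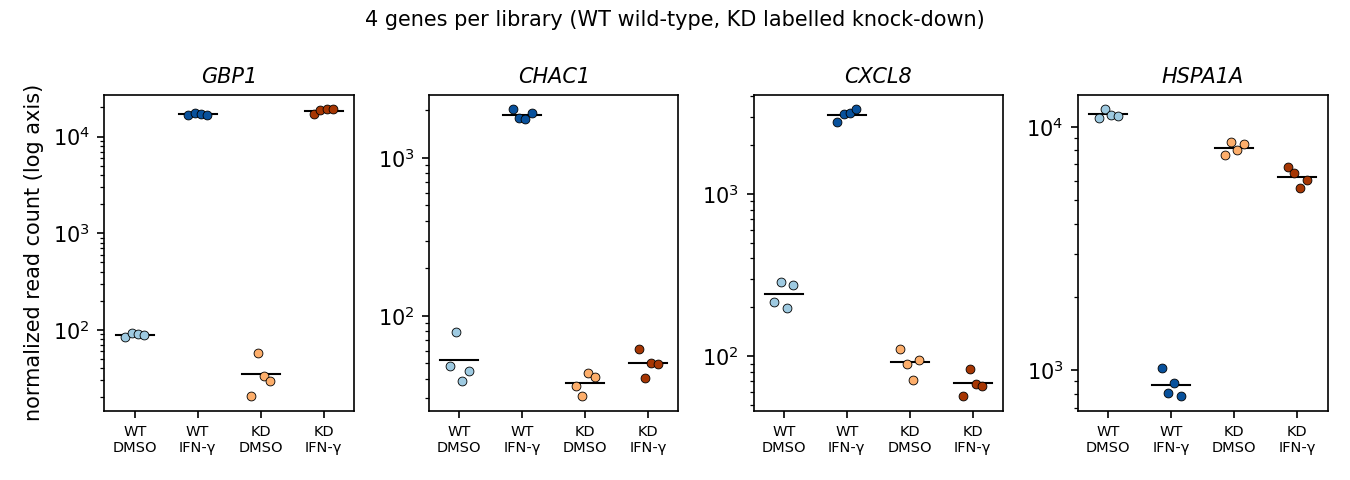
Normalized read counts of GBP1, CHAC1, CXCL8 and HSPA1A per library on log axes, with 4 libraries (points) and their mean (line) for each of the 4 groups; WT is wild-type and KD labelled knock-down. GBP1 is high in both IFN-γ groups (17025 and 18594), CHAC1 and CXCL8 are high only in wild-type cells under IFN-γ (1871 and 3082), and HSPA1A is low there (871).

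Without the cytokine the libraries labelled knock-down and the wild-type libraries differed less. Besides IDO1, the amino-acid transporter gene SLC7A8 was 21.8-fold lower in the libraries labelled knock-down (9.93 ± 6.68 against 217 ± 32.9; SD, n = 4), the growth factor FGF5 7.71-fold and the teneurin TENM2 11.5-fold lower. Higher were CDH23 (14.2-fold, 262 ± 11.2 against 18.4 ± 6.84), the contactin CNTN6 (5.72-fold) and NRN1 (5.15-fold). In total 2911 of 17246 genes passed, 1376 higher and 1535 lower, with 145 and 220 of them at least 2-fold. The share of higher calls, 47.3%, was 50.6% after quantile normalization and 56.6% after removal of the trend with GC content and length. At an adjusted p of 0.01 the count was 1718.

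The IFN-γ effectors were lower at baseline in 15 of 22 cases (17 adjusted over the list alone, camera adjusted p = 3.2e-18), with GBP2 3.22-fold, GBP1 2.52-fold and APOL3 2.49-fold lower and IRF1 at -0.36. NRF2 targets were lower in 13 of 20 cases (13 adjusted over the list alone, camera adjusted p = 2.1e-10), including AKR1B10 (-1.73) and HMOX1 (-1.08), the heme oxygenase. Amino-acid response genes were lower in 14 of 34 cases and higher in 1 (16 lower adjusted over the list alone, camera adjusted p = 5.3e-07), including PHGDH (3.59-fold) and DDIT4 (2.82-fold), and ATF4 stood at -0.33. Also lower were AHR targets (5 lower and 1 higher of 10; 5 lower adjusted over the list alone, camera adjusted p = 0.0014), with CYP1B1 at -0.68. Hypoxia and glycolysis genes were lower as well (7 of 20; 9 adjusted over the list alone, camera adjusted p = 4.4e-06), such as EGLN3 (-2.19). The tryptophan and kynurenine enzymes were called lower (3 of 10; 3 adjusted over the list alone, camera adjusted p = 0.0018), but not without IDO1 itself, a test chosen after seeing the data (2 of 9, camera adjusted p = 0.071). The 3 were IDO1, QPRT (-0.39) and IL4I1 (-1.21), whose adjusted p of 0.0071 became 0.051 without replicate 3 of the labelled knock-down DMSO libraries, 0.11 with thinned reads and 0.087 with the 8 libraries of these groups alone. NF-κB targets were called lower (7 lower and 2 higher of 17; 8 lower adjusted over the list alone, camera adjusted p = 0.0013), with adjusted p = 0.088 with an estimated correlation, and CXCL8 was 2.66-fold lower. Mitotic genes were higher in 6 of 25 cases (6 adjusted over the list alone, camera adjusted p = 0.0013), such as AURKB (0.34), and S-phase genes in 6 of 24 (7 adjusted over the list alone, camera adjusted p = 0.0014, and adjusted p = 0.097 with an estimated correlation). Beside them 12 of 13 mitochondrially encoded transcripts were higher (13 adjusted over the list alone, median 0.27, camera adjusted p = 5.1e-12, and adjusted p = 0.088 with an estimated correlation). In the same libraries 5 of 12 immediate early stress genes were lower (5 adjusted over the list alone, camera adjusted p = 7.3e-04, and adjusted p = 0.12 with an estimated correlation). Among adhesion and mesenchymal genes, not called as a list (4 higher and 6 lower of 23; 4 and 7 adjusted over the list alone, camera adjusted p = 0.85), the fibronectin gene FN1 fell by 1.51 on the log2 scale and EPCAM was 0.84 higher. Of the 28 lists, 4 were higher and 13 lower, but 1 and 6 with an estimated correlation.

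Of the genes higher in the libraries labelled knock-down under DMSO 825 were also higher under IFN-γ, against 342 for independent lists, and 709 were lower under both, against 369. No library enters both comparisons. The labels do not say how many independent knock-down lines were made, so differences between the populations other than IDO1 are not separated from those of the knock-down.

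Whether the response to IFN-γ itself differed between the populations was tested as the difference of the responses, labelled knock-down minus wild-type. The amino-acid response to the cytokine was weaker in the cells labelled knock-down. STC2 rose from 13.2 ± 1.11 to 421 ± 45.6 (SD, n = 4) in wild-type cells and stood at 27.3 ± 8.98 and 27.8 ± 2.31 in those labelled knock-down (difference -4.81, SE 0.32, adjusted p = 1.8e-14), and TRIB3, a pseudokinase induced by ATF4, behaved alike (340.0 ± 37.4 to 4137 ± 229 against 246 ± 30.1 and 240.5 ± 20.7; difference -3.64). HSPA1A, which fell to 871 ± 108 from 11238 ± 403 in wild-type cells, went from 8219 ± 459 to 6222 ± 521 in the others (difference 3.29). The response was stronger for TNFSF10, the gene of the death ligand TRAIL, which went from 74.3 ± 11.7 to 239 ± 36.6 in wild-type cells and from 26.5 ± 6.09 to 691 ± 70.5 in those labelled knock-down (difference 3.00). In total 5699 of 17246 genes passed, 2890 with a higher and 2809 with a lower response in the cells labelled knock-down, with 537 and 411 of the differences at least 2-fold. The share of higher values, 50.7%, was 53.2% after quantile normalization and 43.1% after removal of the trend with GC content and length.

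Of the amino-acid response list 30 of 34 genes had a lower response and 0 a higher one (30 lower adjusted over the list alone, camera adjusted p = 1.0e-36, median -1.64), including CHAC1 (-4.77), GDF15 (-4.17) and ATF4 (-1.95). NF-κB targets had a lower response in 13 of 17 cases (14 adjusted over the list alone, camera adjusted p = 6.2e-15), such as CXCL8 (-4.09), IL6 (-3.33) and TNFAIP3 (-2.79), while ICAM1 stood at -0.28 (adjusted p = 0.64). tRNA synthetases had a lower response in 14 of 19 cases and a higher one in 1 (15 lower adjusted over the list alone, camera adjusted p = 3.3e-12), and WARS1 differed the other way (0.42, or 0.13 after quantile normalization, which did not pass). AHR targets were called lower (5 lower and 2 higher of 10; 6 lower adjusted over the list alone, camera adjusted p = 0.026), with adjusted p = 0.066 with an estimated correlation, and AHR itself differed by -1.24. Cholesterol synthesis genes had a higher value in 20 of 23 cases (22 adjusted over the list alone, camera adjusted p = 5.1e-21) and S-phase genes in 21 of 24 (21 adjusted over the list alone, camera adjusted p = 1.5e-11). So did IFN-γ effectors in 14 of 22 (15 adjusted over the list alone, camera adjusted p = 1.6e-09) and class I processing genes in 17 of 22 (18 adjusted over the list alone, camera adjusted p = 8.6e-09). Examples are INSIG1 (1.94), CCNE2 (1.24), GBP2 (2.27) and CALR (0.69). For the IFN-γ effectors much of this lies in the baseline, since 15 of 22 were lower under DMSO in the libraries labelled knock-down. Under IFN-γ that list was not called between the populations (10 higher and 5 lower, camera adjusted p = 0.15). Type I interferon response genes were called higher (12 of 29, and 15 adjusted over the list alone, camera adjusted p = 1.0e-05). With an estimated correlation the camera adjusted p of that list was 0.22. Mitochondrially encoded transcripts lay beside these groups (6 of 13 higher; 7 adjusted over the list alone, camera adjusted p = 0.0052, and adjusted p = 0.45 with an estimated correlation). The class II genes were not called (5 higher and 1 lower of 16; 5 and 1 adjusted over the list alone, camera adjusted p = 0.16). Other large differences were those of KLHL14 (3.16), HSPA2 (2.84), the sugar transporter SLC2A12 (2.89), IL1A (-5.07) and ADM2 (-3.75). IDO1 had the largest positive difference among genes named by the rule (3.54), which rests on its low level under DMSO in the libraries labelled knock-down.

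Of the 4667 genes that rose in wild-type cells 2425 had a lower response in the cells labelled knock-down, and 1745 of these were not called there. Of the 4365 that fell 2149 had a higher value of the difference. The wild-type libraries enter both tests. With those libraries split into 2 sets of 2, so that the tests shared none of them, the overlaps were 1614 to 1728 and 1338 to 1446. For independent lists they would be 439 to 460 and 386 to 422. The difference subtracts the wild-type response, so such an overlap can be foreseen without shared libraries wherever the responses are not alike. It is therefore no separate support for a weaker response.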

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

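The 3 tests on the IDO1 transcript, the removal of the trend of GC content and length, the thinned reads and the list of endoplasmic reticulum genes were chosen only after the data were seen.

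The IFN-γ response differed between the populations, by the limma test of the difference of the responses, for 80 of the 116 genes the text names and for 5699 genes in all. Labelled knock-down minus wild-type on the log2 scale, the difference was IDO1 3.54, HSPA1A 3.29, KLHL14 3.16, HSPA1B 3.13, WDR72 3.10, TNFSF10 3.00, SLC2A12 2.89, HSPA2 2.84, AKR1B10 2.46, EGLN3 2.36, GBP2 2.27, SLC47A2 2.13, IL7R 2.00, RASSF9 1.96 and INSIG1 1.94. It was smaller for IFIT1 1.94, APOL3 1.86, GBP4 1.76, HSPA8 1.72, HMCN1 1.57, HMGCS1 1.55, GBP1 1.53, HSD17B7 1.421, CDH23 1.39, CCNE2 1.24, NRN1 1.18, GBP5 1.16, HSPE1 1.01, PCNA 1.00 and MVK 0.92, and for CYP1B1 0.88, AKR1C3 0.83, FEN1 0.82, CIITA 0.75, HSP90AA1 0.72, QPRT 0.70, CALR 0.69, IRF1 0.65, TAPBP 0.61, HMOX1 0.53, SNHG14 0.52, PSMB9 0.43, TAP1 0.43, WARS1 0.42, KIF20A 0.41 and FN1 0.21. The response was lower in the cells labelled knock-down for INHBE -5.24, KLHDC7B -5.22, IL1A -5.07, STC2 -4.81, CHAC1 -4.77, GDF15 -4.17, CXCL8 -4.09, ADM2 -3.75, TRIB3 -3.64, IL6 -3.33, TNFAIP3 -2.79, DDIT4 -2.65, ATF3 -2.45, EREG -2.34, PHGDH -2.28, ETV5 -2.11 and ATF4 -1.95. It was also lower for SNHG15 -1.80, CARS1 -1.75, FOSL1 -1.70, SNHG5 -1.68, ZFAS1 -1.63, GARS1 -1.62, SNHG17 -1.58, DUSP4 -1.56, AARS1 -1.36, AHR -1.24, XBP1 -0.98, SLC7A11 -0.92, ADAMTS5 -0.67, HERPUD1 -0.57, SELENOS -0.41, HSF1 -0.40 and PLK1 -0.22. The values of genes with few reads in a group, such as INHBE, KLHDC7B, RASSF9 and GBP4, depend on the pseudocount and bound nothing, and that of KLHDC7B did not pass with edgeR (adjusted p = 1.00). The call of WDR72 was lost in 11 of the 16 fits that left out a library, with adjusted p up to 0.064. IDO1 itself went against the label under IFN-γ, so these directions rest on the label.

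For IFN-γ against DMSO, the real grouping was the only 1 of 35 to call as many genes, 9032 in wild-type cells (highest other 1) and 4875 in those labelled knock-down (highest other 0). The same held between the populations under IFN-γ (8433, 1 of 35, highest other 0) and under DMSO (2911, 1 of 35, highest other 3). For the difference of the responses the real grouping was the only 1 of 100 to call as many (5699), with 5239, 5174 and 5027 in regroupings that left the IFN-γ libraries in place and exchanged only DMSO libraries, and 93 at most in the others. In the comparisons between groups the real grouping of these libraries thus stood out, though 1 of 35 is the smallest share such splits can give. Every other split mixes the groups compared, which widens the spread within each side, so low counts there could be foreseen. The splits cannot speak to chance between cultures or lines, since the libraries of a group may be technical. For the difference of the responses the regroupings test for any difference between the populations, not for this difference alone. With 5239 calls when only DMSO libraries were exchanged, they cannot exclude chance for that count. Those regroupings kept the difference under IFN-γ, where most of these calls may therefore lie.

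The level of the IDO1 transcript was low in the libraries labelled knock-down under DMSO (-3.34) and not under IFN-γ (0.20). If the libraries labelled knock-down under IFN-γ were mislabelled wild-type cells, the 2910 other genes that differed under DMSO would not differ there, but in the direction they had under DMSO their median difference under IFN-γ was 0.24, and 70.1% of them kept it against 56.6% of the genes not called under DMSO. Over 3 other scalings the lowest IDO1 difference under IFN-γ was 0.21, so the choice among these scalings does not account for it. None of them can show a change in RNA per cell. Only 0.565% of 177 genes induced at least 4-fold in wild-type cells (IL7R, named after its value was seen) lay as far below wild-type under DMSO as IDO1. Their median difference was -0.21. Genes near the lower limit of that set, a wild-type DMSO mean of 10, had to lose nearly all reads to fall so far. The IFN-γ effectors were lower under DMSO too, in 15 of 22 cases. Whether a lower interferon activity was the whole cause is therefore not decided. A candidate explanation is a knock-down that acts on the basal transcript and is overrun, or acts after transcription, once IFN-γ induces the gene. It was not tested, since neither the protein nor the method of the knock-down is given in the sources used here.

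The amino-acid response list had a lower response in the cells labelled knock-down (median -1.64). The median was -1.65 after the trend of GC content and length was removed and -1.61 on thinned reads, which argues against both as the cause. Stress of the endoplasmic reticulum in wild-type cells would raise the list of its genes, but their median change under IFN-γ was -0.054. The 95% bootstrap interval over the genes, which treats them as independent, was -0.20 to 0.15. Of the 21 genes 9 fell and 6 rose, 3 of them by at least 0.5 (XBP1 1.21, HERPUD1 0.65 and SELENOS 0.62, named after their values were seen). This argues against a rise of these genes as a group in wild-type cells. In the cells labelled knock-down 11 of the 21 rose and 0 fell (camera adjusted p = 6.0e-06, and 0.017 with an estimated correlation). Many of the 21 genes are chaperones, so a stress that raises ATF4 without raising chaperones is not excluded. A candidate explanation is a shortage of tryptophan from IDO1 activity in wild-type cells only, which would need less active enzyme behind a similar transcript level in the other cells. It was not tested, since no level of tryptophan, kynurenine or IDO1 protein is among the data used here. Differences between the populations other than IDO1 stay open, as untested.

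In 36 of 464 groups of 4 libraries of the genes named, 1 library stood apart by Dixon's ratio of its gap to the range (critical value 0.829), where chance flags about 1 in 20 groups, or 23.2. In 10 of them the other 3 libraries had no read, which fixes the ratio at 1, and without the 21 groups with at least 3 such libraries 26 of 443 stood apart against 22.1 by chance. Among wild-type DMSO libraries these were AIM2 in replicate 4 (1, 3.18 against a median of 0 in the others), APOL4 in replicate 2 (0.844, 9.58 against a median of 0 in the others), CYP1B1 in replicate 1 (0.915, 6528.7 against a median of 6084.6 in the others), GBP4 in replicate 1 (1, 1.08 against a median of 0 in the others) and HLA-DRB1 in replicate 3 (1, 3.00 against a median of 0 in the others). In the same group these were also HSP90AA1 in replicate 2 (0.917, 53548.8 against a median of 55995.4 in the others), PCNA in replicate 1 (0.838, 3642.9 against a median of 3917.4 in the others), SLC15A3 in replicate 2 (1, 4.79 against a median of 0 in the others) and SLC7A8 in replicate 1 (0.965, 167.3 against a median of 232.4 in the others). Among wild-type IFN-γ libraries these were ADAMTS5 in replicate 2 (0.924, 254.9 against a median of 224.9 in the others), AHR in replicate 4 (0.850, 963.2 against a median of 1144.7 in the others), APOL3 in replicate 1 (0.920, 1456.8 against a median of 1342.3 in the others), BNC1 in replicate 1 (0.842, 60.6 against a median of 47.0 in the others), CALR in replicate 2 (0.961, 14636.2 against a median of 15898.3 in the others) and CNTN6 in replicate 1 (0.868, 15.2 against a median of 5.38 in the others). In the same group these were also EGLN3 in replicate 2 (0.851, 37.7 against a median of 18.1 in the others), IL1A in replicate 1 (0.831, 783.0 against a median of 988.0 in the others), RASSF9 in replicate 2 (1, 1.79 against a median of 0 in the others), TAPBP in replicate 1 (0.861, 6827.7 against a median of 6494.5 in the others) and WDR72 in replicate 4 (0.919, 0 against a median of 16.7 in the others). Among labelled knock-down DMSO libraries these were EREG in replicate 1 (0.954, 28.4 against a median of 6.28 in the others), HLA-DRB1 in replicate 3 (1, 1.20 against a median of 0 in the others), HMCN1 in replicate 4 (0.850, 211.9 against a median of 152.1 in the others), IFI44L in replicate 2 (0.935, 9.31 against a median of 0 in the others) and IL1B in replicate 1 (0.845, 7.73 against a median of 0 in the others). In the same group these were also IL7R in replicate 2 (1, 3.10 against a median of 0 in the others), INHBE in replicate 3 (1, 1.20 against a median of 0 in the others), SLC15A3 in replicate 3 (1, 1.20 against a median of 0 in the others) and SLC7A8 in replicate 4 (0.860, 0 against a median of 12.9 in the others). Among labelled knock-down IFN-γ libraries these were BNC1 in replicate 4 (1, 2.31 against a median of 0 in the others), CGB2 in replicate 2 (0.902, 44.3 against a median of 15.3 in the others), GBP1 in replicate 1 (0.874, 17259.7 against a median of 19076.2 in the others) and IL7R in replicate 3 (0.842, 70.2 against a median of 49.7 in the others). In the same group these were also NRN1 in replicate 2 (0.848, 402.9 against a median of 327.2 in the others), SLC2A12 in replicate 3 (0.862, 103.8 against a median of 95.3 in the others) and TNFSF10 in replicate 1 (0.899, 585.4 against a median of 729.5 in the others). The most in a library, in wild-type IFN-γ replicate 1, were 5.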

How the results depend on the processing

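The fits without the 5 shallowest libraries, on thinned reads and with the trend of GC content and length removed, the tryptophan enzymes without IDO1 and the heat-shock list without 3 genes were chosen only after the data were seen. Under the alternative thresholds, filters, scalings and tools, the counts of changed genes stayed within 1.5 times the reported ones except where the threshold itself was narrowed. With a change of at least 2-fold required they were 1738 for IFN-γ in wild-type cells, 865 in those labelled knock-down, 1268 between the populations under IFN-γ, 365 under DMSO and 948 for the difference of the responses. At an adjusted p of 0.01 the count under DMSO was 1718. Both follow from the narrower threshold. The balance of higher and lower calls turned in every comparison under quantile normalization, the removal of that trend or both, so it rests on the scaling.

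In the same order, edgeR on the recovered reads called 9183, 5016, 8748, 2966 and 5889 genes and DESeq2 9285, 5177, 8852, 3138 and 6015. Without the 5 libraries under 13000000 reads the counts were 8930, 3772, 8395, 2032 and 5189, and on thinned reads 8644, 4547, 8055, 2577 and 5366, with the largest relative loss under DMSO both times. Leaving out each library in turn gave 8507 to 9299, 4188 to 5001, 7868 to 8723, 2352 to 2950 and 5291 to 5785. The IDO1 difference then ran from -3.48 to -3.15 under DMSO and from 0.19 to 0.22 under IFN-γ, with the smallest p the exact permutation test allows in each case.

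Of the list tests, fry called 26 lists between the populations under IFN-γ against 10 with camera, and 24 for the difference of the responses against 12, since it does not compare a list with other genes. With an estimated correlation camera called 7 lists under DMSO against 17, and 7 for the difference of the responses against 12. Lists still called could have far larger values. For the IFN-γ effectors in the cells labelled knock-down the camera adjusted p was 2.9e-06 against 3.8e-62. The cause was not tested.

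Among 859 values of named genes, 420 calls were lost and 172 gained over the 16 alternatives, and 181 and 87 over the 16 fits that left out a library. Of the 420, 236 were lost where a change of at least 2-fold was required and 51 at an adjusted p of 0.01. These losses follow from the narrower threshold. Under quantile normalization 2 turned direction: ENO1, a glycolytic enzyme, between the populations under IFN-γ (0.08 to -0.25), and WARS1 there (0.27 to -0.012). The cause was not tested. The fit of 8 libraries alone does not apply to the difference of the responses. All other alternatives planned were run.

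With the replicate number as a replicate block the counts were 9057, 4884, 8466, 2938 and 5735, and 3 values of named genes passed and 5 no longer passed. In an exact paired sign-flip test over the 4 numbers the IDO1 differences of -3.34 under DMSO and 0.20 under IFN-γ had p = 0.125, the smallest 4 pairs can give. Deviations from the group mean correlated between -0.07 and 0.07 over the 24 pairs of libraries with the same number, and 10 of 24 comparisons placed a library closest to its own number. Over genes with a mean of at least 100 they ran from -0.24 to 0.26, with 4 of the 24 over 0.1, against 11 of 72 pairs with different numbers and up to 0.27 there. These 4 were all pairs of a wild-type and a labelled knock-down library under the same treatment (0.26 and 0.16 under DMSO, 0.21 and 0.24 under IFN-γ). The other same-number pairs of that kind lay between -0.07 and 0.02. Pairs of that kind with different numbers reached at most 0.07 under DMSO and 0.12 under IFN-γ. The 11 of 72 are pooled over all pairs of groups and so are not the matching measure. A block shared by all groups need not take up a pairing within a treatment, so such a pairing stays open. The labels give the libraries only a number in common.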

Other observations

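The 6 gene lists of this part and of the endoplasmic reticulum test were chosen only after values of these data were seen, the heat-shock list because of HSPA1A, HSPA1B and HSPA2, which are among its members. The test of host genes of small nucleolar RNAs was written before the values of its members were seen and left out the host genes already looked at.

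Heat-shock genes fell further in wild-type cells, and MAPK feedback genes rose there. Without the 3 genes that prompted the list, a test added later still, 16 of 18 targets of the heat-shock factor HSF1 fell under IFN-γ in wild-type cells and 0 rose (camera adjusted p = 2.7e-11). In the cells labelled knock-down 5 fell and 1 rose (camera adjusted p = 0.012, and adjusted p = 0.077 with an estimated correlation), and the difference of the responses was higher for 15 and lower for 1 (camera adjusted p = 2.2e-10). The chaperone gene HSPA8 went from 34146 ± 749 to 8922 ± 703 in wild-type cells (SD, n = 4) and from 33704 ± 1900.2 to 28972 ± 1345 in the others, and HSP90AA1 and HSPE1 stood at -0.77 and -1.07 on the log2 scale in wild-type cells. Of 15 genes that feed back on or report MAPK signalling, 10 rose in wild-type cells and 0 fell (camera adjusted p = 5.3e-07), while 3 rose and 8 fell in those labelled knock-down (camera adjusted p = 0.0055, and adjusted p = 0.077 with an estimated correlation). The difference of the responses was lower for 12 of them and higher for 0 (camera adjusted p = 4.0e-15), including, named after their values were seen, the phosphatase DUSP4 (-1.56), the transcription factor ETV5 (-2.11) and FOSL1 (-1.70). Part of it lies in the baseline, since under DMSO 8 of them were higher in the libraries labelled knock-down and 1 lower (camera adjusted p = 3.3e-05). Autophagy and lysosome genes (4 higher and 5 lower of 20, camera adjusted p = 0.98) and translation factors (1 and 3 of 15, camera adjusted p = 0.39) were not called for that difference. Endoplasmic reticulum chaperones were called higher (11 and 3 of 21, camera adjusted p = 5.5e-04).

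Host genes of small nucleolar RNAs, whose spliced transcripts are known targets of nonsense-mediated decay when translated, were higher in wild-type cells under IFN-γ. Over 21 host genes the median difference of the responses was -0.78, with 12 lower and 1, SNHG14, higher, outside the range of -0.23 to 0.22 that holds the middle 95% of 10000 random lists of the same size and mean level. Among them ZFAS1, SNHG5, SNHG15 and SNHG17, like SNHG14 named after their values were seen, stood at 1.81, 1.87, 1.91 and 1.62 in wild-type cells and at -1.63, -1.68, -1.80 and -1.58 in the difference. The median of that difference over 1907 long non-coding RNA genes was 0.16, which argues against a general rise of such RNAs in wild-type cells. A candidate explanation is slower nonsense-mediated decay in wild-type cells under IFN-γ, which may go with the amino-acid response seen there, but no decay rate was measured and the IDO1 transcript under IFN-γ did not follow the knock-down label.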
